A study of Mus musculus with 12 samples.

How the data were processed

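Total RNA from 12 kidneys of male C57BL/6J mice at postnatal day 28 was labelled with biotin and hybridised to Illumina arrays carrying 45281 probes. The labels put 6 samples in the control group and 6 in the group whose mothers drank 10% (v/v) ethanol at will from fertilization to gestation day 8.5. Per the labels' protocols, RNA was extracted with a QIAGEN column kit and its integrity was checked before labelling. The deposited values are probe intensity on a linear scale, with the background subtracted, so that 8.16% to 33.3% of the values of an array lay below 0. Per the submitters' processing notes the values came from GenomeStudio, Illumina's array software. Its version, the way the background was subtracted and any scaling between arrays are not given in the sources used here. The median deposited intensity was 14.2, 17.4, 16.4, 25.7, 17.8 and 21.1 in control samples 1 to 6 and 18.7, 26.2, 22.8, 16.6, 20.9 and 16.1 in ethanol samples 1 to 6.

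A second table of signals and detection p-values was not used here, because its column names match no sample's label. Its 24 columns of values per sample were left out of every step. The design fixed before the data were examined had foreseen that table, with its detection p-values for the background correction and for the filter. The background was therefore estimated from the deposited intensities themselves. For each array the mode of the values (kernel density with a bandwidth of 2, sought below the 0.6 quantile) was taken as the background mean and the spread below the mode as its SD. A normal-exponential correction with these parameters and an offset of 16 was followed by quantile normalization and log2 in limma 3.58.1 under R 4.3.3. This background stands in for negative control probes, and an error in it would move dim probes most. A probe counted as above background on an array where the normal probability of its value was under 0.05, and it was tested where this held on at least 6 of 12 arrays. Of the 45281 probes, 23984 were tested. The number of arrays limits the precision.

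Gene symbols came from the platform annotation. It gave 1 symbol for 34885 probes, several for 18 and none for 10378, and no gene was named from a probe with several. The gene numbers of 34807 probes were found in the mouse RefSeq gene table of assembly GRCm38.p6, which was used for names only and altered 0 symbols. A gene was represented by its probe with the highest mean over the 12 arrays, which gave 12618 genes, and 2348 of the 5009 genes with more than 1 tested probe had probes that differed in sign.

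The comparison was ethanol minus control in limma (lmFit and eBayes), with Benjamini-Hochberg adjustment over the tested probes and an adjusted p under 0.05 as a call. Gene lists fixed before the data were examined were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over 33 lists. The spread between samples was compared as the median log2 ratio of SDs, with a permutation of group-centred values over all 924 assignments. Named genes were chosen by a rule fixed before the data were examined. With fewer than 10 genes past the threshold, it takes the 10 higher and 10 lower genes with the smallest unadjusted p, given as values, and up to 4 members of each list with the smallest p. For lists that passed no threshold, members were named only at an unadjusted p under 0.05, a restriction added later. Predicted and clone names were left out.

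On simulated data with the spread of the 23984 tested probes, the test called 71 percent of probes changed by 1 on the log2 scale and 21 percent of those changed by 0.5, with 4 false calls. These were 71 and 21 probes. The noise was independent between probes, and the share called depends on how many are changed. The shares therefore do not carry over to the real samples. In a simulation of 12618 independent genes, camera called 5 of 5 lists shifted by -0.3 and 0 of 25 lists with no shifted member; real genes of a list are correlated, which this simulation leaves out. Alternatives covered no background correction, an offset of 50, median scaling, the deposited values as they stand, no filter and a strict one, averaged probes, array quality weights, a variance prior with trend (robust for probes, with statmod 1.5.0; trend alone in camera), a replicate block, each array left out, and an estimated correlation, fry or an exact permutation for the lists. No sample was left out of the main comparison. The probes are given by gene symbol without positions, since no genome build is given in the sources used here.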

Results

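Gene expression was measured in whole kidneys of male C57BL/6J mice at postnatal day 28, an inbred laboratory strain, to find which genes differ between offspring exposed to ethanol in utero and controls. There were 6 control and 6 ethanol samples, each on 1 array. Between 50.4% and 56.9% of the probes lay above background on an array, with a mean of 53.7% ± 1.81 (SD, n = 6) in controls and 53.1% ± 1.72 (SD, n = 6) in ethanol samples (exact permutation p = 0.626, two-sided). Correlations between arrays ran from 0.952 to 0.992 over the tested probes. The labels do not say which dam or litter a sample came from, nor that the samples are separate animals, so p-values measure only the spread between these samples.

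No single gene separated the ethanol kidneys from the controls after adjustment. The genes with the smallest unadjusted p included Itfg1, at 6.34 ± 0.47 on the log2 scale in ethanol against 5.25 ± 0.40 in controls (SD, n = 6 each; log2 difference 1.09 ± 0.22 SE), and Slf1, at 7.34 ± 0.39 against 6.35 ± 0.41. Dzank1 (log2 difference 0.70), Tenm2 (0.80), Lonrf3 (0.87), Dusp11 (0.51), Apool (0.60), Zfp382 (0.63), Slc17a2 (0.58) and Olfr1160 (0.49) were the other genes on the higher side. On the lower side stood the splicing factor gene Srsf11 (-0.65), Sh2d2a, which encodes a T cell adapter (-0.91), the interleukin 1 receptor gene Il1r1 (-0.50), the tropomyosin gene Tpm3 (-0.71), the histone acetyltransferase gene Kat6a (-0.67), Vgll4 (-0.59), the receptor gene Ror1 (-0.64), Arid5b (-0.95) and Klri1 (-0.46). Fez1 was above background in 6 of 6 controls and 0 of 6 ethanol samples, which makes it at least 1.13-fold higher in controls, set against the lowest signals above background. Of the other tested probes, 2 of 3 of Srsf11 (0.46 and 0.45) and the 1 each of Lonrf3 (-0.06) and Arid5b (0.17) had the opposite sign, and the remaining Srsf11 probe gave -0.51. The second probe was smaller on the same side for Itfg1 (0.25), Dusp11 (0.32), Slc17a2 (0.18) and Tpm3 (-0.03). Several of these genes were dim, so their differences are set partly against background: in controls Olfr1160 was above background in 1 of 6 samples, Apool in 2, Zfp382 in 3 and Itfg1 in 4. In ethanol samples Sh2d2a was above background in 1 of 6, Arid5b and Klri1 in 4, and Il1r1, Ror1 and Olfr1160 in 5, and Sh2d2a was so in 5 of 6 controls. The size of such differences depended on the handling of background: without background correction Sh2d2a differed by -4.83, Fez1 by -2.59, Itfg1 by 1.68, Olfr1160 by 1.66 and Apool by 1.58. The same held for Cyp11a1 (2.23), Cd3d (-1.95), Igfbp6 (-1.84), Mbd2 (1.69) and Krt19 (-1.58) of the lists below, and with the deposited values as they stand for Zfp382 (1.43) and Cdc25c (1.62). With the probes of a gene averaged, Srsf11 fell to -0.06 and Slc13a3 to -0.21.

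In limma, 0 of 23984 probes passed an adjusted p under 0.05, and the smallest adjusted p was 0.301. At an unadjusted p under 0.05 there were 2923 probes, 1287 higher and 1636 lower in ethanol, where 1199 are expected by chance. The excess does not exclude chance, since 7 of 100 splits of the arrays, the real one included, gave at least 2923. The number fell to 1807 without ethanol 2 and to 1832 without ethanol 3. The lean to lower turned with the deposited values as they stand (1116 higher, 1081 lower) and without control 4 (1436 higher, 1243 lower). The groups did not overlap for 60 genes, 0.476% of those tested, where chance gives 0.216%. Group membership held 14.8% of the variance over the tested probes (exact permutation p = 0.0563, two-sided over all assignments). The first principal component over the tested probes held 32.6% of the variance. Its mean was 14.4 ± 25.4 in ethanol and -14.4 ± 28.9 in controls (SD, n = 6 each, exact permutation p = 0.0974, two-sided). Ethanol 2 and 3 lay at its high end (45.6 and 37.5) and control 4 at its low end (-62.5). Hk1, Pcx, Eng, Myl9, Calr, Gnas, Acadl and Slc13a3, named below under several lists, were lowest in ethanol 2 and 3. Their differences need not be separate.

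Genes of immune cells were lower in ethanol kidneys by a set test with a preset correlation. Of the 24 genes in the lymphocyte and plasma cell list, 16 were on the array and 7 were tested. None of its immunoglobulin or J chain genes was among the 7, so plasma cells were hardly covered. All 7 tested members lay below 0, with a median log2 change of -0.52 (camera with preset correlation, adjusted p = 0.00044, or 0.00946 with no filter on dim probes). The members were not alike: Cd8b1, the brightest at 12.9 in controls, differed by only -0.12, and Ccl5 by -0.83 with a control SD of 1.46. In 5 of 6 ethanol samples the list mean lay below that of every control. The call of this list was lost with an estimated correlation (adjusted p = 0.718). Controls 4 to 6 stood apart from the other controls, with list means of 0.32, 0.43 and 1.04 against -0.06, -0.05 and -0.08 for controls 1 to 3, so much of the gap lay with them. Coro1a, an actin regulator of leukocytes, was 7.86 ± 0.24 in ethanol against 8.38 ± 0.29 in controls (SD, n = 6 each), and its other probes gave -0.27 and -0.94. Cd3e, a chain of the T cell receptor complex, was 5.35 ± 0.21 against 6.08 ± 0.66, and the lymphocyte surface gene Cd52 was 8.10 ± 0.32 against 8.51 ± 0.22. These 3 genes passed when adjusted over the list alone, and 0 passed over all probes. Cd3d differed by -0.63 and was above background in 2 of 6 ethanol samples. The macrophage and myeloid list had 19 of 22 members below 0 and a median of -0.12 (camera, adjusted p = 0.00407; adjusted p = 0.718 with an estimated correlation), with 0 members called either way. Its members with the smallest p were the complement genes C1qc (-0.35), C1qb (-0.29) and C1qa (-0.32) and the antigen presentation gene H2-Eb1 (-0.33). Other markers in the list lay near 0, among them Ptprc (0.09), Mrc1 (0.08), Ctss (0.02), Csf1r (-0.04), Lyz2 (-0.03) and Adgre1 (-0.08). Without ethanol sample 6 the myeloid list had an adjusted p = 0.0725.

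4 other lists were lower in ethanol by camera with the preset correlation. None of them passed with an estimated correlation, at an adjusted p = 0.718 for each. Cytosolic ribosomal proteins had 27 of 37 members below 0 (median -0.06, adjusted p = 0.0146), among them Rps6 (-0.41), Rpl27 (-0.47), Rps9 (-0.30) and Rps15 (-0.30). The interstitial fibroblast and extracellular matrix list had 16 of 22 below 0 (median -0.08, adjusted p = 0.0279), with the intermediate filament gene Vim at -0.47, the fibronectin gene Fn1 at -0.48 (-0.12 by another probe), Tgfbi at -0.26 and Sparc at -0.24. The other 2 tested probes of Sparc gave -1.42 and 0.02. The interferon response list had 21 of 29 below 0 (median -0.12, adjusted p = 0.0338), with Irf7 (-0.40), Isg15 (-0.38), Bst2 (-0.35) and Oas1g (-0.29). The cholesterol and lipid synthesis list had 14 of 22 below 0 (median -0.11, adjusted p = 0.0429), with the transcription factor gene Srebf1 (-0.48), Nsdhl (-0.50, with 3 other probes from -0.48 to -0.01), Dhcr7 (-0.37) and Sqle (-0.25). No member of these 4 lists was called over all probes or adjusted over the list alone. The call was lost for the ribosomal list without control 1, control 3, ethanol 2 or ethanol 6 (adjusted p from 0.0537 to 0.174) and for the matrix list without control 1, control 2, ethanol 1 or ethanol 6 (0.0537 to 0.270). It was lost for the interferon list without 7 of the 12 arrays in turn (controls 1, 2, 3 and 5 and ethanol 4, 5 and 6; 0.0513 to 0.152) and for the cholesterol list without 8 (controls 1, 3, 5 and 6 and ethanol 1, 2, 3 and 5; 0.0502 to 0.261).

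**Figure D1:**
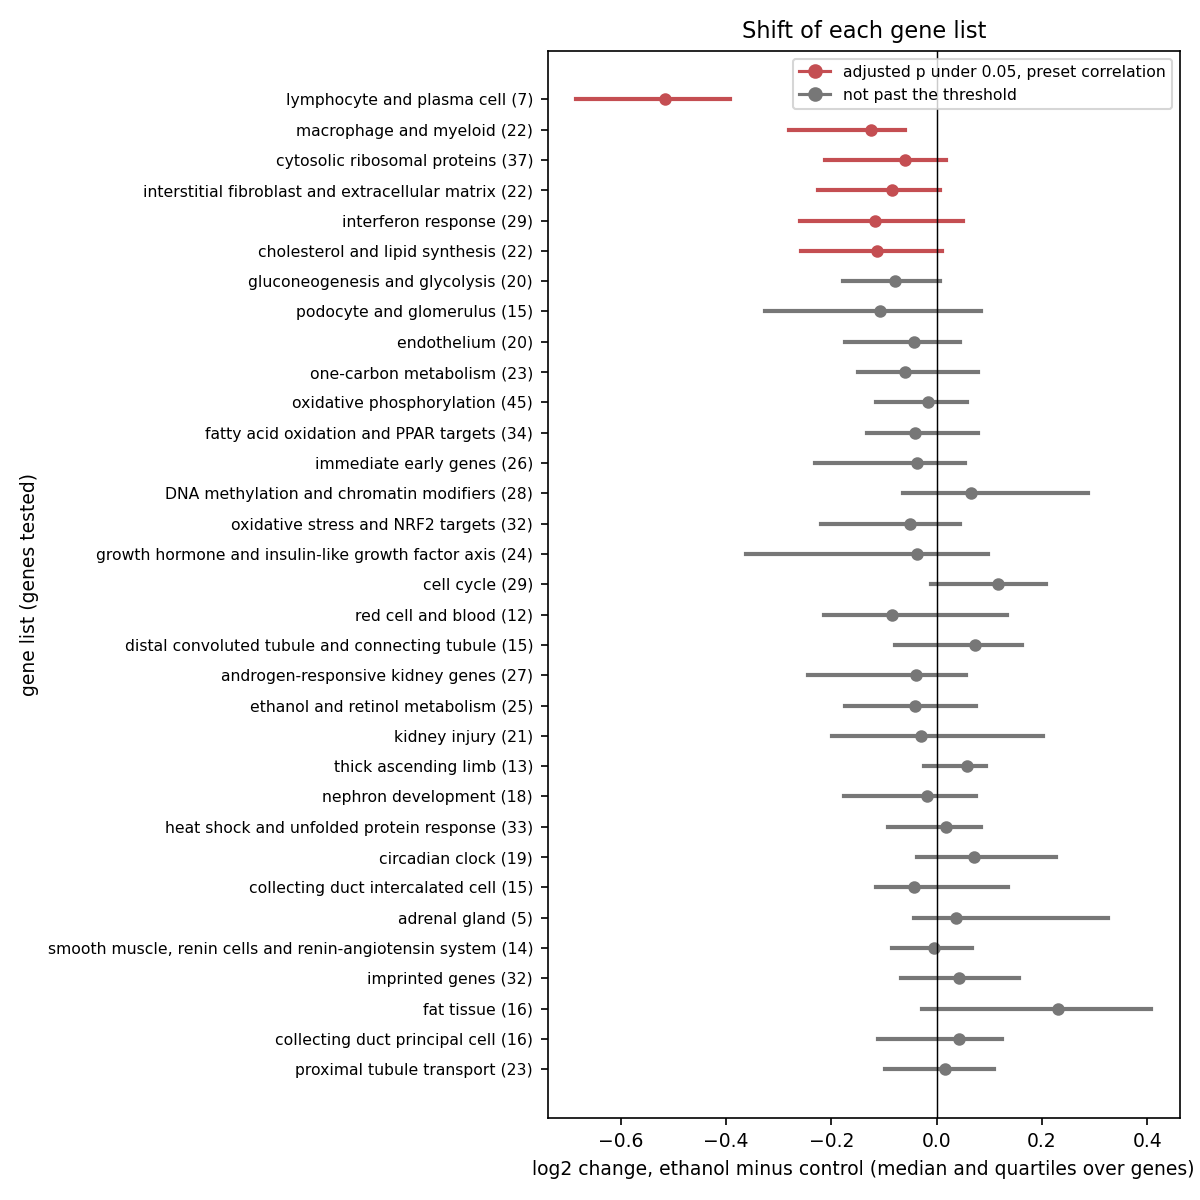
Median log2 change (ethanol minus control, horizontal axis) of each gene list with its quartiles over genes as bars; the number of genes tested stands beside each list's name. The lymphocyte and plasma cell list lies farthest from 0, at a median of -0.52, and the 6 lists past the threshold with the preset correlation (adjusted p = 0.718 for each with an estimated one) lie below 0.

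Single genes of other lists passed only when adjusted over the list alone. That adjustment takes 1 list at a time and makes no allowance for the 33 lists searched. In the oxidative stress and NRF2 list (32 genes, median -0.05, camera adjusted p = 0.282), the heme oxygenase gene Hmox1 differed by -0.86 ± 0.23 (SE) from a control level of 7.86 ± 0.42, and the metallothionein gene Mt2 was 7.35 ± 0.38 in ethanol against 6.55 ± 0.32 in controls (SD, n = 6 each). Those 2 genes passed over the list alone; Mt1 (0.36) and Sod3 (-0.48) did not. In the growth hormone and insulin-like growth factor list (24 genes, median -0.04, adjusted p = 0.282), the binding protein gene Igfbp3 was 10.7 ± 0.38 against 11.4 ± 0.26 and was the 1 gene to pass over the list alone, with Igfbp6 (-0.61, above background in 3 of 6 ethanol samples), Igfals (-0.36) and Socs2 (-0.49) on the same side. Of its members 14 lay below 0 and 10 above, and at an unadjusted p under 0.05 there were 5 lower and 1 higher. In the DNA methylation and chromatin list (28 genes, median 0.07, adjusted p = 0.241), the methyl-CpG binding protein gene Mbd2 passed over the list alone, at 5.53 ± 0.21 against 4.94 ± 0.27. It was above background in only 2 of 6 controls, so this difference is set mostly against background. Kmt2a (0.44), Tet1 (0.54) and Eed (0.40) lay on the same side, and a second probe of Eed gave -0.07. Of its members 17 lay above 0 and 11 below, and at an unadjusted p under 0.05 there were 6 higher and 1 lower. In the podocyte and glomerulus list (15 genes, median -0.11, adjusted p = 0.101), Clic5 passed over the list alone, at 6.90 ± 0.15 against 7.33 ± 0.18, with Tcf21 (-0.49) and the nephrin gene Nphs1 (-0.47) below 0, while 7 members lay above 0. None of these genes passed over all probes.

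**Figure D2:**
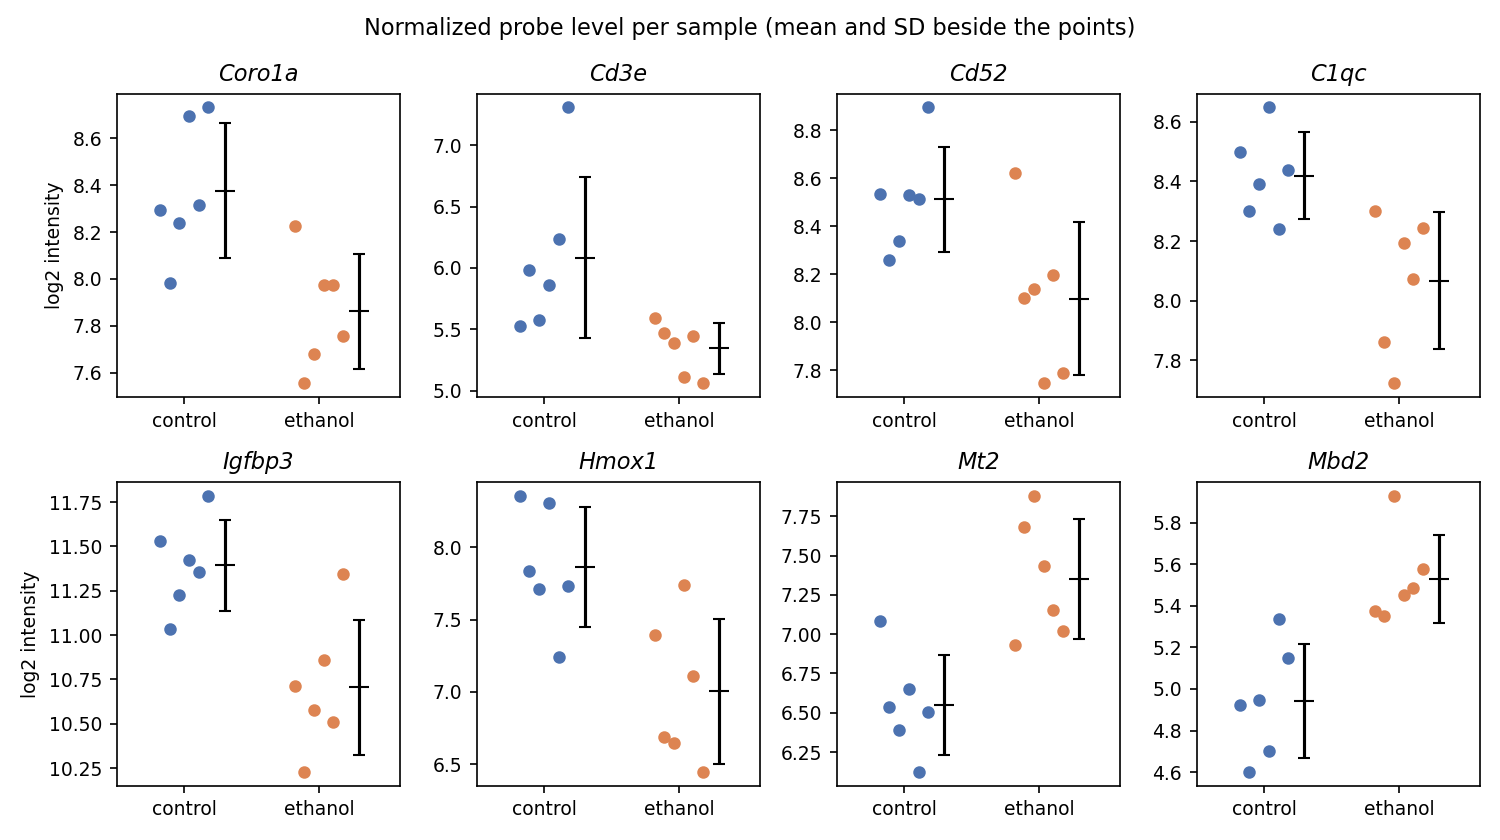
Normalized log2 intensity (vertical axis) of 8 genes in each of the 6 control and 6 ethanol samples, with the group mean and SD beside the points. The groups overlap for Hmox1, while for Mbd2 the ethanol samples lie above the controls, of which 2 of 6 were above background.

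Markers of the nephron segments did not pass. Proximal tubule transport genes (23 tested) had a median of 0.02 and an adjusted p = 0.889; their mean lay below 0 against the other genes, at -0.06, and the direction of the test turned under 2 of 5 settings of background and scaling. Slc9a3 differed by 0.33, Slc13a1 by 0.62 and Slc13a3 by -0.81, with 1 of 3 Slc13a3 probes of opposite sign (0.84) and the remaining 1 at -0.66. The thick ascending limb list (13 genes) had a median of 0.06 and an adjusted p = 0.432, as had the distal convoluted and connecting tubule list (15 genes, median 0.07), where Trpm7 differed by 0.62. The collecting duct principal cell list (16 genes, median 0.04, adjusted p = 0.807) included the water channel gene Aqp3 at -0.38, and its test pointed below 0 while its median lay above. The intercalated cell list (15 genes, median -0.04, adjusted p = 0.546) included the carbonic anhydrase gene Car2 at -0.46, with a second probe at 0.16. Endothelial genes (20 tested) had a median of -0.04 and an adjusted p = 0.114, with Cldn5 at -0.49, Eng at -0.74 and Pecam1 at -0.47 (-0.19 and -0.10 by its other probes). Smooth muscle, renin cell and renin-angiotensin genes (14 tested) had a median near 0 (adjusted p = 0.566), with Myl9 at -0.75. The nephron development list (18 genes, median -0.02) had an adjusted p = 0.523.

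Apart from cholesterol and lipid synthesis, metabolic and stress lists did not pass either. Gluconeogenesis and glycolysis (20 genes, median -0.08) had an adjusted p = 0.093, with Pcx at -0.62 and Hk1 2.01-fold higher in controls (above background in 5 of 6 ethanol samples). Hk1 was lowest in ethanol 2 and 3 (5.11 and 5.53), against 8.07 in control 4 and 7.71 in ethanol 6. One-carbon metabolism (23 genes, median -0.06), oxidative phosphorylation (45 genes, median -0.02), fatty acid oxidation and PPAR targets (34 genes, median -0.04) and immediate early genes (26 genes, median -0.04) each had an adjusted p = 0.241. Members with unadjusted p under 0.05 in these were Folr1 (-0.48), Cth (-0.44), Chdh (-0.45), Uqcrc1 (-0.38), Sdhb (-0.30), Decr2 (-0.59), Acadl (-0.56, with 1 of 3 probes of opposite sign) and Nfkbiz (0.69). Ethanol and retinol metabolism (25 genes, median -0.04) had an adjusted p = 0.432, with Adh5 at -0.53 by 1 probe and 0.31 by another. The cell cycle list (29 genes, median 0.12, adjusted p = 0.282) held Cdc25c (0.52), Ccna2 (0.45), Ccne1 (0.39) and Tyms (-0.30, with 2 of 4 probes of opposite sign). Of 6 controls, Cdc25c and Ccne1 were above background in 5 and Ccna2 in 4. Heat shock and unfolded protein response genes (33 tested, adjusted p = 0.523) had a median of 0.02 although the test pointed below 0, with Calr at -0.73, Hyou1 at -0.52, Chordc1 at 0.43 and Dnajc3 at 0.33. The kidney injury list (21 genes, median -0.03, adjusted p = 0.432) held Vim (-0.47), Cxcl1 (0.56) and Krt19 (-0.52, above background in 5 of 6 controls and 2 of 6 ethanol samples). The circadian clock list (19 genes, median 0.07, adjusted p = 0.546) held Wee1 (0.47). Imprinted genes (32 tested, median 0.04, adjusted p = 0.635) held Ppp1r9a (0.70), Kcnq1ot1 (0.99), Copg2 (-0.45) and Gnas (-0.66, with 3 of 6 probes of opposite sign).

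Lists of tissue that can lie in or beside a kidney gave no call. Red cell and blood genes (12 tested, median -0.08) had an adjusted p = 0.326, adrenal genes (5 tested, median 0.04) 0.566, with Cyp11a1 at 0.46 (above background in 3 of 6 controls; 0.17 by a second probe), and fat tissue genes (16 tested, median 0.23) 0.674. The androgen-responsive list (27 genes, median -0.04, adjusted p = 0.432) also did not pass. Samples of 1 group differed widely in some genes of the last 2 lists, while others, such as the androgen-responsive gene Kap (15.2 to 15.7), varied little. Cyp2j13 ran from 4.76 to 10.6 on the log2 scale over the 12 samples and Acsm3 from 8.45 to 13.1, while the adipokine gene Adipoq ran from 5.02 to 10.8 and Ucp1, the uncoupling protein of brown fat, from 4.53 to 11.1.

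**Figure D3:**
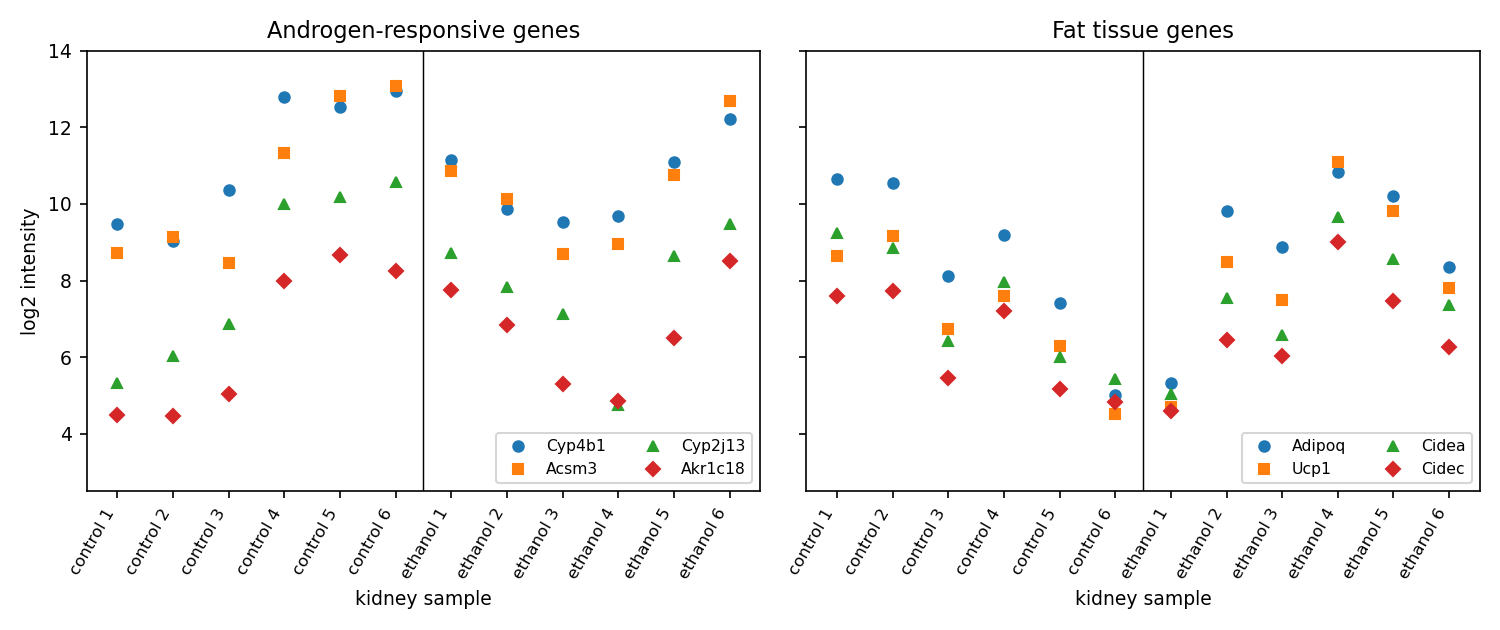
Normalized log2 intensity (vertical axis) of 4 androgen-responsive and 4 fat tissue genes in each kidney sample (horizontal axis); the vertical line parts controls from ethanol samples. Adipoq was lowest in control 6, at 5.02, and highest in ethanol 4, at 10.8.

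No difference in the spread between samples passed the test. The median log2 ratio of the SD in ethanol over that in controls was -0.14 (permutation p = 0.634, two-sided, over 924 assignments). The genes that check the male label gave Kdm5d at 8.83 ± 0.23 in controls and 9.05 ± 0.13 in ethanol, Eif2s3y at 11.5 ± 0.78 and 11.9 ± 0.10, and Uty at 7.26 ± 0.46 and 7.55 ± 0.28 (SD, n = 6 each), all above background on 12 of 12 arrays. Xist was above background on 1 of 12 arrays.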

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

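The tests of the blood, the lowest-weight arrays, array quality, androgen exposure and fat were chosen only after the result was seen. The lymphocyte and plasma cell list, lower in ethanol, had 1 sample far from its group: ethanol 1 was highest, with a gap of 0.627 of the group's range. The controls also fell apart, with controls 4 to 6 at 0.32, 0.43 and 1.04 and controls 1 to 3 between -0.08 and -0.05. Arrays brighter at the low end in one group are argued against, as the lymphocyte mean stood at percentile 0 and the myeloid mean at 0.02 of 10000 random lists matched on level. Random genes vary together less than the members of these lists, so the percentiles overstate how unusual the lists were. The lymphocyte difference did not rest on the 2 arrays with the lowest weights, control 4 and ethanol 6, without which the mean difference was -0.51 against -0.53. Blood left in the kidney stays open: within groups the list followed 5 red cell genes with a Spearman's rho of -0.32 (permutation p = 0.303) and a Pearson's r of -0.53 (p = 0.0763), but without the 2 farthest samples rho was 0.14 and r was -0.28, and the stricter reading was chosen after that value was seen. The list's own exact permutation gave p = 0.0281, or 0.339 adjusted over lists. That test did not single the list out, as 4 lists had an exact permutation p under 0.05. The growth hormone and insulin-like growth factor list, not called by camera, had a smaller one (0.0238, also 0.339 adjusted). For the number of lists called, chance was not excluded: 47 of 100 splits of the 12 arrays, the real one included, called at least the real 6, and the highest other split called 15. An effect of the exposure stays open as well, untested beyond this comparison.

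Some androgen-responsive genes varied widely within groups, and the first principal component of their list held 85.6% of its variance against a 95th percentile of 59.0% in random lists. Steep genes weigh most in it: per SD of the component Cyp2j13 rose by 1.89 and Acsm3 by 1.66 on the log2 scale. Other members barely followed it or went the opposite way, among them Kap (-0.003), Gusb (0.03), Cyp7b1 (-0.04) and Hao2 (-0.25). On this component controls 4 to 6 (1.08 to 1.42) lay apart from controls 1 to 3 (-1.22 to -0.77), as on the lymphocyte list, while ethanol samples ran from -1.03 to 1.09 with no such break by number. What parts these controls stays open. Array quality was not decided. The component had a Spearman's rho of -0.33 with the array weights (permutation p = 0.297, Pearson's r -0.30, p = 0.349), and rho was -0.56 without the 2 farthest samples. A weight falls with distance from the group in either direction, which a correlation with a signed component can miss. The share was 86.0% without the 2 arrays of lowest weight, so the pattern did not rest on those 2. A different share of proximal tubule stays open, with a slope of the transport genes 0.274 of the list's. Samples may also have come from different stages of androgen exposure: 3 of 4 genes higher in female kidney (Slc7a12, Abcc3 and Cyp4a14) went against the component and Slc22a7 went along with it, which leaves that hypothesis undecided.

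Fat genes went together across samples, with 87.5% of the list's variance on 1 component against a 95th percentile of 65.7% in random lists. This is consistent with fat carried along with some kidneys, and no biological explanation was tested.

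Of 364 groups of values examined, 21 had a sample far from the others, where chance alone gives about 1 in 20. The gap as a share of the group's range was 0.675 for Dzank1 in control 6, 0.678 for Itfg1 in ethanol 6, 0.775 for Sh2d2a in ethanol 1, 0.817 for Vgll4 in control 4, 0.790 for Trpm7 in control 6 and 0.775 for Ppp1r9a in ethanol 1. It was 0.669 for Tyms in ethanol 1, 0.662 for Kmt2a in control 6, 0.694 for Cxcl1 in control 6 and 0.679 for Chordc1 in ethanol 5. Among androgen-responsive genes it was 0.648 for Timd2 and 0.692 for Hao2 in ethanol 6, 0.685 for Tmigd1 in control 4 and 0.638 for Gusb in ethanol 2. The Y-linked gene Eif2s3y was lowest in control 4 (0.817), and Uty was lowest in control 4 (0.736) and in ethanol 6 (0.629). Lists with such a sample were one-carbon metabolism (ethanol 6, 0.754), fatty acid oxidation (ethanol 4, 0.660) and heat shock (control 4, 0.642).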

How the results depend on the processing

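The run without 2 arrays, the androgen covariate and the exact permutation of lists were added after seeing the data. In limma 0 probes passed under every setting but the deposited values as they stand, which called 1 unnamed probe (adjusted p = 0.00821), not past the threshold in the main setting (0.301). Averaged probes gave 1343 of 12618 genes at an unadjusted p under 0.05 against 2923 of 23984 probes, a smaller share as well as a smaller number. Leaving out 1 array gave 1807 (without ethanol 2) to 3775 probes. For each of 96 named genes the direction held in all 2260 values. The genes were picked for a small p in these samples and mostly kept the same probe, so this was nearly bound to hold. Other probes of some named genes went the opposite way, as for Adh5 (0.31 against -0.53) and Tyms (0.42 against -0.30). The spread ratio ran from -0.30 to 0.13 without 1 array, none past the threshold.

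By camera with the preset correlation, leaving out 1 array left 2 to 10 lists, with 2 without control 1 or ethanol 6 and 10 without ethanol 4. Of those 10 lists 9 were lower in ethanol, and the cell cycle list was higher (adjusted p = 0.0124). The adjusted p ran from 3.2e-05 to 0.00394 for lymphocytes, 3.2e-05 to 0.0725 for myeloid genes, 0.00142 to 0.174 for ribosomal proteins, 0.00327 to 0.270 for matrix, 0.00061 to 0.152 for interferon and 0.00142 to 0.261 for cholesterol. It ran from 0.0317 to 0.273 for podocytes, 0.00446 to 0.474 for endothelium, 0.0124 to 0.605 for cell cycle, 0.0106 to 0.536 for fatty acid oxidation, 0.0277 to 0.203 for glycolysis, 0.0277 to 0.494 for oxidative stress and 0.0430 to 0.785 for immediate early genes. With an estimated correlation, fry or exact permutation 0 lists passed. The estimated correlation gave 0.718 for each of the 6; fry gave 0.362 for lymphocytes, 0.630 for myeloid genes and 0.695 for the other 4; exact permutation gave 0.339 for lymphocytes, 0.4375 for myeloid, interferon and ribosomal genes and 0.643 for matrix and cholesterol. The cholesterol list was lost with the deposited values (0.0545), the strict filter (0.0639) and averaged probes (0.0826), and the interferon list with the strict filter (0.0639). Lists gained were oxidative phosphorylation (0.0199) and glycolysis (0.0455) with the deposited values, glycolysis with the trended prior (0.0415), podocytes with array weights (0.0382) and without the 2 arrays (0.0207), one-carbon metabolism without the 2 arrays (0.0430) and endothelium with the androgen covariate (0.0475). The cause was not tested.

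With a replicate block 0 probes and 7 lists passed, glycolysis added at 0.0447. In limma the smallest adjusted p was 0.0705 with the block against 0.301 without it. At an unadjusted p under 0.05 there were 3557 probes with the block against 2923. The labels do not say that equal numbers pair samples. Correlations of same-numbered deviations were 0.0009, 0.46, 0.07, 0.05, 0.07 and 0.02. Of the controls, only control 2 correlated best with its own number (0.46 against 0.44 for the best other). Pairing was thus neither shown nor excluded. A slide block was not run, as the columns name no slide. Signal over background limits dim probes: Cd3d was above background in 2 of 6 ethanol samples.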

Other observations

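The tests of splits were fixed before their results were seen; the genes and probes below were chosen after their values were seen. Genes outside the fixed list went with the androgen-responsive component across the 12 samples. With group in the model, 293 probes passed an adjusted p under 0.05 in limma for this component, 216 of them higher with it. Mfsd2a, a lipid transporter gene, ran from 7.18 to 11.2 on the log2 scale, Nat8 from 10.3 to 13.3 and Chst7 from 8.47 to 11.2, while Serpina6, the gene of corticosteroid-binding globulin, went the opposite way, from 14.5 down to 10.8. The component was built from the same samples, so the count describes them and is no independent test. Ccl5, a member of the lymphocyte list, was among these genes; with the component as a covariate the lymphocyte list had an adjusted p = 0.00019 at the preset correlation. Without the covariate, the list did not pass with an estimated correlation (adjusted p = 0.718), fry (0.362) or exact permutation (0.339), and these were not run with it.

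An unnamed probe had the largest difference among unnamed probes. ILMN_2638923 was 13.3 ± 0.83 in controls and 10.0 ± 2.07 in ethanol samples (SD, n = 6 each), 9.69-fold higher in controls, with limma's adjusted p = 0.379. The ethanol samples ran from 7.60 to 13.3, so the groups overlapped. Ethanol 1, at 13.3, lay at the control level; the fold was 15.3 without it and 6.91 without ethanol 6. ILMN_1230073 was 3.91-fold higher in controls, also with an adjusted p = 0.379.

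The real grouping was set against other splits of the 12 arrays into 6 and 6. Of 100 splits, the real one included, 7 had at least the real 2923 probes at an unadjusted p under 0.05, and the highest other had 4571, so chance was not excluded. For probes past the adjusted threshold the splits decide nothing, since the real count was 0 and all 100 splits reach that by construction. The highest other split called 119 probes, which points to some structure of the samples, although it was picked as the highest and no value says how high that would be without one. That split put control 1, control 2 and ethanol 2 to 5 on one side. On the fat component these ran from -0.28 to 1.64 and the other 6 from -1.54 to 0.15, and on the androgen-responsive component from -1.22 to 0.10 and from -0.77 to 1.42. The sides overlapped on both, so neither was singled out.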
